A study of Rattus norvegicus with 18 samples.

How the data were processed

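Total RNA from laser-captured regions of 3 subcutaneous 9L tumours and from 9L cultures was amplified and hybridized to Affymetrix Rat Gene 1.0 ST arrays, per the labels. The deposited values are log2 probe set signals made with RMA in Partek 6.5b, per the submitters' processing notes. Whether all 18 arrays were normalized together, and which annotation was used, is not given in the sources used here. The values ran from 2.16 to 13.8, array medians from 6.36 to 6.50 in tumour samples and from 6.02 to 6.19 in cultures, and the SD over probe sets from 1.76 to 1.92 in tumour samples and from 2.04 to 2.17 in cultures. No 2 arrays were identical, and 319 probe sets shared all 18 values with another.

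Gene symbols came from the platform's annotation table, which lists 15420 of the 27363 probe sets. Of these, 15097 carry exactly 1 symbol and 323 several, and the other 11943 probe sets were tested without a gene name. Symbols were checked by Entrez ID against a rat gene table (15067 matched, 0 updated). Where a gene had more than 1 probe set (499 genes), the one with the highest mean over all 18 arrays stood for it, which gave 14324 genes. Tests over all probe sets used every probe set.

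Tests were run in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all 27363 probe sets and a threshold of adjusted p = 0.05. Tumour regions were compared in a fit of the 6 tumour arrays with the tumour as a fixed block. Culture responses at 6 h and 16 h came from a fit of the 12 culture arrays in 4 groups, and the difference between both times was an interaction contrast in it. The difference between the tumour response and the mean culture response was an interaction contrast over all 18 arrays with 9 pairs as blocks. Normoxic tumour regions were compared with normoxic cultures in a fit of 18 arrays in 6 groups. These designs, the gene lists and the rule for named genes were fixed before the data were examined.

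The 21 lists, 13 of pathways and 8 of cell types, hold 355 members, of which 311 were measured. Those not measured were not analysed here. The pathway lists are glycolysis and glucose uptake, other textbook HIF targets, unfolded protein and integrated stress response, mitosis, DNA replication, homologous recombination and mismatch repair, oxidative phosphorylation and TCA cycle, cholesterol synthesis, extracellular matrix, p53 targets, interferon response, inflammatory cytokines and NF-kB targets, and immediate early genes. The cell type lists are markers of macrophages, T and NK cells, neutrophils, endothelium, pericytes and smooth muscle, skeletal muscle, adipocytes, and glial and neural stem cells. Lists were tested with camera (limma) at its preset correlation of 0.01 on 1 probe set per gene, adjusted over the 21 lists of a comparison, with camera at an estimated correlation and fry beside it. camera compares a list with the other genes, and fry asks whether its members move one way on balance. Members were also counted adjusted over the list alone.

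Named genes were, in the tumour, 6 h and 16 h comparisons, the 10 largest changes per direction among genes past the threshold that moved the same way in all 3 pairs, filled up by unadjusted p where fewer passed, and the 4 members of each list with the smallest p. In the other contrasts they were the 5 largest per direction among genes past the threshold. Vegfa, Slc2a1, Car9, Hif1a and Epas1 were named in any case. List members taken by this rule are named only where their list passed camera in that comparison, a restriction made after the data were examined. The alternatives of the genes and lists left unprinted are summarised with the other alternatives.

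Whether culture numbers pair the cultures was checked by correlating the deviations of same-numbered arrays from their group means. These were 0.125, 0.193 and 0.192 at 6 h and 0.130, 0.188 and 0.307 at 16 h, and 0.128, 0.0357 and 0.273 for the tumours, which are paired by design. The highest correlation of each normoxic array with a hypoxic array of another number was 0.177, 0.00437 and 0.0187 at 6 h. It was -0.0246, -0.0584 and -0.0763 at 16 h, and 0.0512, 0.167 and -0.0711 for the tumours. For culture 6 and for tumour 2 it exceeded the same-numbered value, so the check does not settle whether culture numbers mark pairs. The block by culture number is given as an alternative.

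The fits were tested on simulated data with spreads drawn from limma's fitted prior, 200 changed probe sets and 10 simulations per comparison. For changes of 0.5, 1, 2 and 4 log2 units, the tumour fit recovered 0, 1.8, 77 and 99.2% with 3.78% false calls. The 6 h fit recovered 24.8, 89.8, 99.6 and 100% (5.48% false), and the 16 h fit 26.6, 90.4, 99.8 and 100% (4.98% false). The difference between both times gave 4.4, 62.6, 97.8 and 100% (4.47% false). The tumour response minus the culture response gave 1.6, 45.8, 92.2 and 99.6% (6.05% false), and normoxic tumours against cultures 22.2, 83, 97.6 and 99.6% (4.67% false). Each simulation mixed equal numbers of these sizes, and large changes ease the adjusted threshold for smaller ones. The shares hold for that mix and do not give the share of real changes that a fit would find. In the real tumour arrays 0 probe sets passed, although Bnip3 differed by 3.2 log2 units. Among 20 random lists of 15 genes, a list shifted by 0.6 log2 units was called in 10 of 10 simulations in the tumour, 6 h and 16 h fits, and lists without a shift in 0, 2 and 0 of 190. The simulated genes varied independently of each other. These counts therefore do not show how often camera with the preset correlation wrongly calls lists whose genes move together.

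The alternatives were the replicate block, each replicate left out, quantile normalization, median centring, cyclic loess, leaving out the dimmest 25% or 50% of probe sets, only probe sets with 1 symbol, a trended and robust variance, array weights, other sets of arrays in the fit, an adjusted p of 0.1, and a log2 change of at least 1. For lists they were the estimated correlation, fry, the block, the mean of a gene's probe sets and scaling. Alternatives added after the data were examined were leaving out replicates for lists, the counts adjusted over the list alone under other settings, a separate spread for tumours and cultures, and scaling for the genes raised in culture. Raw array files were not used here.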

Results

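Gene expression was measured in 9L, a rat gliosarcoma line that is used as a glioma model, as tumours in Fischer rats and as cells in culture. EF5 is a nitroimidazole that binds inside cells at low oxygen. In each of 3 tumours, an area without EF5 binding (the normoxic region) and an area with EF5 binding (the hypoxic region) were taken by laser capture, in which chosen areas of a section are lifted out under the microscope. Cultured 9L cells were held at about 20% or at 0.2% oxygen for 6 h or 16 h, with 3 cultures in each of the 4 groups. The 18 samples were read on Affymetrix Rat Gene ST arrays as log2 values of 27363 probe sets, and the number of arrays limits the precision. Arrays of one group correlated at 0.937 to 0.964 across probe sets in the tumour groups and at 0.988 to 0.996 in the culture groups. The labels do not say whether the cultures of a group were separate experiments, so p-values for cultures measure the spread between these samples, which may be technical.

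The first comparison asked which genes differ between hypoxic and normoxic tissue of the same tumour. Hypoxic regions held more transcript of genes for glucose use and of other targets of the hypoxia-inducible factors (HIF). They held less transcript of genes for mitosis, DNA replication, DNA repair and cholesterol synthesis, and less of macrophage, T cell and interferon genes. These lists passed limma's camera with its preset correlation, and none passed with an estimated correlation (adjusted p = 0.291 to 0.430 with an estimated correlation) or by fry (adjusted p = 0.135 to 0.305). Bnip3, a mitophagy receptor, was 9.22-fold higher in hypoxic regions, at a log2 difference of 3.21 ± 0.37 (SE, n = 3 tumours). Car9, the carbonic anhydrase that serves as a marker of tumour hypoxia, was 3.83-fold higher at 1.94 ± 0.19. No single gene passed the test over all probe sets, so the gene values of this comparison are given as measured and not as calls. limma found 0 probe sets at adjusted p = 0.05, with a smallest adjusted p of 0.106. At unadjusted p under 0.05 there were 2496, of which 937 were higher and 1559 lower, where chance gives 1368.2.

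The 20 measured genes of glycolysis and glucose uptake lay 0.95 ± 0.42 log2 units higher in hypoxic regions (SD over 3 tumours), 19 of them in that direction. Adjusted over the list alone, 13 were higher, and 8 without tumour 1. The glycolytic enzymes Aldoa and Pfkl were 1.46 ± 0.18 and 1.46 ± 0.22 higher (SE), and Pfkfb3, which makes the activator of phosphofructokinase, was 1.29 ± 0.19 higher. The glucose transporter Slc2a1 was 1.90 ± 0.55 higher, at 3.44, 2.01 and 0.26 in tumours 1, 2 and 3, and 1.13 higher without tumour 1. The 29 other HIF targets lay 1.08 ± 0.37 higher (SD over 3 tumours), 28 of them in that direction, with 19 higher when adjusted over the list alone. Among them were Ndrg1 at 2.06 ± 0.22, the angiogenic factor Vegfa at 1.75 ± 0.22 and the endoplasmic reticulum oxidase Ero1a at 2.05 ± 0.30. Both lists passed limma's camera with its preset correlation (adjusted p = 5.36e-13 and 5.84e-17). Neither passed with an estimated correlation (adjusted p = 0.291 for both with an estimated correlation). Of the oxygen-regulated subunits themselves, Hif1a was at 0.39 ± 0.26 (SE), with 1.07, 0.12 and -0.02 in tumours 1, 2 and 3 and 0.05 without tumour 1. Epas1 was at 0.12 ± 0.18, at 0.06 to 0.21 with a tumour left out and at -0.0037 after cyclic loess.

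**Figure D1:**
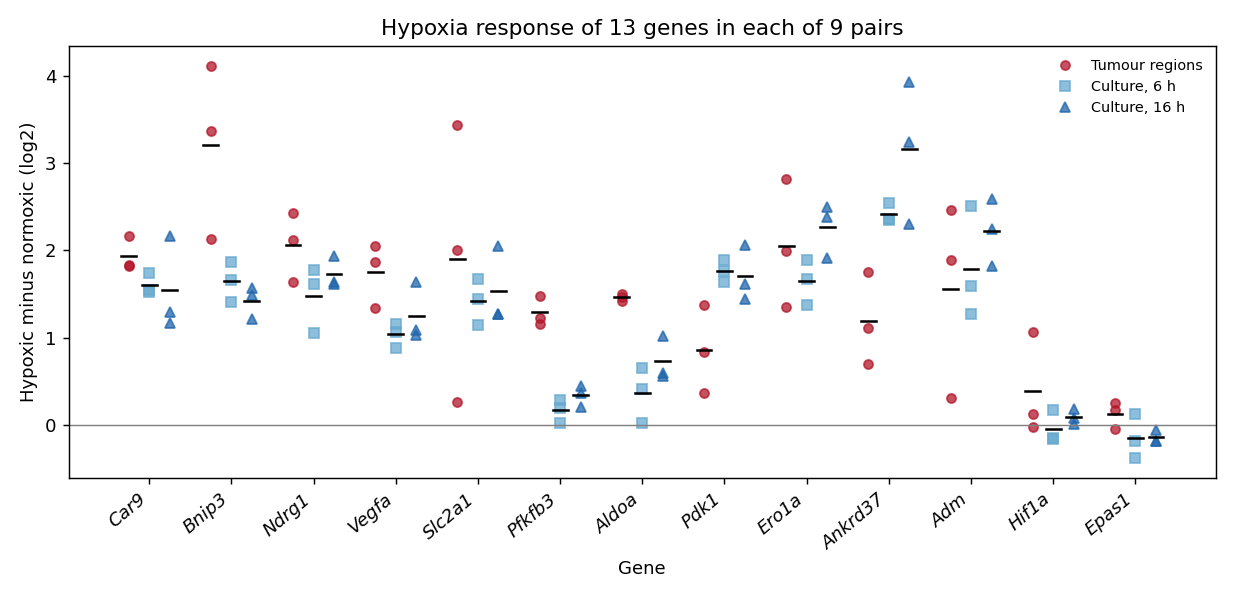
Change of 13 genes between hypoxic and normoxic samples (y axis, log2) in each of 3 tumours, 3 pairs of 6 h cultures and 3 pairs of 16 h cultures, with 1 point per pair and a black bar at the mean. Car9 lay above 0 in all 9 pairs, with means of 1.94 in tumours, 1.60 at 6 h and 1.54 at 16 h, while Hif1a lay at 1.07, 0.12 and -0.02 in tumours 1, 2 and 3.

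The 17 mitosis genes lay -0.79 ± 0.28 log2 units from their normoxic level (SD over 3 tumours), 16 of them lower. Adjusted over the list alone, 13 were lower, and 0 without tumour 3. Cyclin A2 (Ccna2) was at -1.42 ± 0.29 (SE), the spindle protein Tpx2 at -1.16 ± 0.23 and the kinase Aurkb at -0.83 ± 0.19. The 19 DNA replication genes lay at -0.54 ± 0.48 (SD over 3 tumours), 15 of them lower, with 6 lower when adjusted over the list alone and 3 without tumour 3. In tumours 1, 2 and 3 that list lay at -0.48, -0.10 and -1.05, and its mean was -0.29 without tumour 3. The lower ones included the sliding clamp Pcna at -1.74 ± 0.20 (SE) and the ribonucleotide reductase subunit Rrm2 at -1.09 ± 0.18. The 8 genes of homologous recombination and mismatch repair lay at -0.61 ± 0.15 (SD over 3 tumours), 7 of them lower. Rad51c at -1.06, Brca2 at -0.91 and Rad54l at -0.81 were the 3 lower ones when adjusted over the list alone, a count of 0 without tumour 1 and of 1 without tumour 2. All 3 lists passed camera with the preset correlation (adjusted p = 1.03e-11, 3.80e-06 and 5.81e-06). With an estimated correlation none did (adjusted p = 0.291, 0.430 and 0.291 with an estimated correlation).

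The 13 genes of cholesterol synthesis lay at -0.71 ± 0.26 log2 units (SD over 3 tumours), 11 of them lower. Adjusted over the list alone, 4 were lower: the sterol dehydrogenase Nsdhl at -1.62 ± 0.20 (SE), squalene epoxidase (Sqle) at -1.48 ± 0.22, the sterol sensor Insig1 at -1.77 ± 0.50 and Mvd. That count was 2 without tumour 3, without the tumour block or after quantile normalization, and Insig1 was at -0.99 without tumour 3. The 19 genes of oxidative phosphorylation and the TCA cycle lay at -0.40 ± 0.40 (SD over 3 tumours), 18 of them lower, with Ndufs1 of complex I alone past the threshold when adjusted over the list alone. That count was 0 without tumour 2 or tumour 3. Camera with the preset correlation gave adjusted p = 6.21e-07 for cholesterol synthesis and 6.80e-06 for oxidative phosphorylation, and the latter call was lost without tumour 3 (mean -0.17, adjusted p = 0.0618). The corresponding values were adjusted p = 0.291 and 0.430 with an estimated correlation.

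Markers of macrophages and of T and NK cells lay lower in hypoxic regions, and most of all in tumour 3. The 16 macrophage markers lay at -0.62 ± 0.43 log2 units (SD over 3 tumours), 13 of them lower. Adjusted over the list alone, 4 were lower: the complement component C1qa at -1.60 ± 0.39 (SE), the pan-leukocyte gene Ptprc at -1.55 ± 0.44, Laptm5 at -1.11 ± 0.31 and the protease Ctss. The 13 T and NK cell markers lay at -0.68 ± 0.55 (SD over 3 tumours), 12 of them lower, with the T cell receptor subunit Cd3d at -2.33 ± 0.51 (SE) alone past the threshold when adjusted over the list alone. The 18 interferon response genes lay at -0.59 ± 0.57 (SD over 3 tumours), 15 of them lower. Adjusted over the list alone, 4 were lower: Cxcl10 at -1.60 ± 0.40 (SE), Gbp2 at -1.60 ± 0.30, Mx1 at -1.51 ± 0.31 and Ifi44 at -1.02 ± 0.25. In tumour 3 the macrophage, T and NK cell and interferon lists lay at -1.09, -1.26 and -1.21, and in tumour 2 at -0.25, -0.17 and -0.08. Their means without tumour 3 were -0.38, -0.39 and -0.29. The sample titles of tumour 3 carry codes that begin with Sp and those of tumours 1 and 2 codes that begin with Ag, and the titles do not explain them. The normoxic array of tumour 3 stood apart from the other tumour arrays, with a correlation of 0.941 with the mean of normoxic cultures against 0.865 to 0.892, and an SD over probe sets of 1.92 against 1.76 to 1.79. Its mean log2 level was 8.26 for interferon genes (7.43 and 7.19 in the normoxic regions of tumours 1 and 2), 7.58 for T and NK cell markers (6.80 and 6.61), 7.98 for DNA replication genes (7.39 and 7.34) and 9.33 for oxidative phosphorylation genes (8.70 and 8.80), so the differences of these lists in tumour 3 depend on that array. It was also the highest for mitosis genes at 8.52 (8.11 and 7.95) and for macrophage markers at 8.57 (8.16 and 8.24). For macrophage markers the hypoxic array of tumour 3 was also the lowest, at 7.48 (7.64 and 7.99 in the hypoxic regions of tumours 1 and 2). The 3 counts adjusted over the list alone were 0 without tumour 3 and after median centring, and those of macrophage and T and NK cell markers were also 0 without the tumour block or after quantile normalization, at means of -0.59 and -0.69 after the latter. Without tumour 1 the counts were 8 for interferon genes and 5 for T and NK cell markers, and without tumour 2 they were 8 and 2. Without tumour 3 the values of C1qa, Ctss, Laptm5 and Cxcl10 were -0.997, -0.88, -0.72 and -1.01. Camera with the preset correlation passed all 3 lists (adjusted p = 5.81e-06, 1.36e-05 and 3.80e-06), but none passed with an estimated correlation (adjusted p = 0.395, 0.291 and 0.430 with an estimated correlation).

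Immediate early genes, which answer growth and stress signals within minutes, lay 0.38 ± 0.31 log2 units higher (SD over 3 tumours), 13 of 15 in that direction. Egr1, at 1.51 ± 0.24 (SE), was the single one past the threshold when adjusted over the list alone. Camera gave adjusted p = 0.00431, against adjusted p = 0.430 with an estimated correlation, and the call was lost without tumour 1 (mean 0.23, adjusted p = 0.0764). The other 10 lists did not pass camera. Neutrophil markers lay at 0.29, with 0.16, 0.11 and 0.61 in tumours 1, 2 and 3. They passed without tumour 1 (0.36, adjusted p = 0.0199) and lay at 0.13 without tumour 3. Glial and neural stem markers lay at 0.17, pericyte and smooth muscle markers at 0.13, adipocyte markers at 0.11, skeletal muscle markers at 0.08 and endothelial markers at 0.06, or at -0.0060 after quantile normalization. Skeletal muscle markers lay at 0.02 after quantile normalization and also without tumour 3. Dim probe sets lay higher in hypoxic regions as a whole, with a median of 0.14 in the dimmest 25% and 0.16 in the next 25%, against -0.13 in the brightest 25%. Relative to genes of the same brightness, a comparison chosen after the result was seen, neutrophil, glial, pericyte, adipocyte, skeletal muscle and endothelial markers lay at 0.17, 0.08, 0.05, 0.01, -0.03 and -0.06. Inflammatory cytokines and NF-kB targets lay at 0.03, extracellular matrix at -0.08 and p53 targets at -0.12. The 19 genes of the unfolded protein and integrated stress response had a mean of 0.09 but a median of -0.15, and camera placed the list lower. Its stress transcription factor Atf3 stood apart at 2.41 ± 0.25 (SE) and was the single member past the threshold when adjusted over the list alone, a count of 3 without tumour 2.

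Several genes outside the lists differed as far as the hypoxia genes did. The surface antigen gene Ly6c was at -2.92 ± 0.24, the mitochondrial carrier Slc25a40 at -2.26 ± 0.23, the centromere protein Cenpk at -2.21 ± 0.22 and the oligosaccharyltransferase subunit Ost4 at -2.19 ± 0.24 (SE, n = 3 tumours). Isocitrate dehydrogenase (Idh1) was at -1.74 ± 0.20 and the uncoupling protein Ucp2 at -1.73 ± 0.20. The heat shock protein Hspb1 was 2.22 ± 0.33 higher and Actr3b 1.36 ± 0.19 higher. The number of calls in tumours changed with the arrays that were fitted. A fit of all 18 arrays with the pair as a block changes both the spread and its degrees of freedom. It called 1408 probe sets (448 higher, 960 lower), among them 51 of the 60 genes named by rule. Most of these genes were chosen by their values in the same tumour arrays, so that overlap is no independent support. This fit pools tumours with cultures, which varied less (median residual SD 0.138 log2 units against 0.236 in tumours), and so can understate the spread of tumours. The count was 563 (154 higher, 409 lower) without tumour 1 and 22 with a trended and robust variance. It was 1 without the dimmest 25% of probe sets and 0 in the remaining alternatives.

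**Figure D2:**
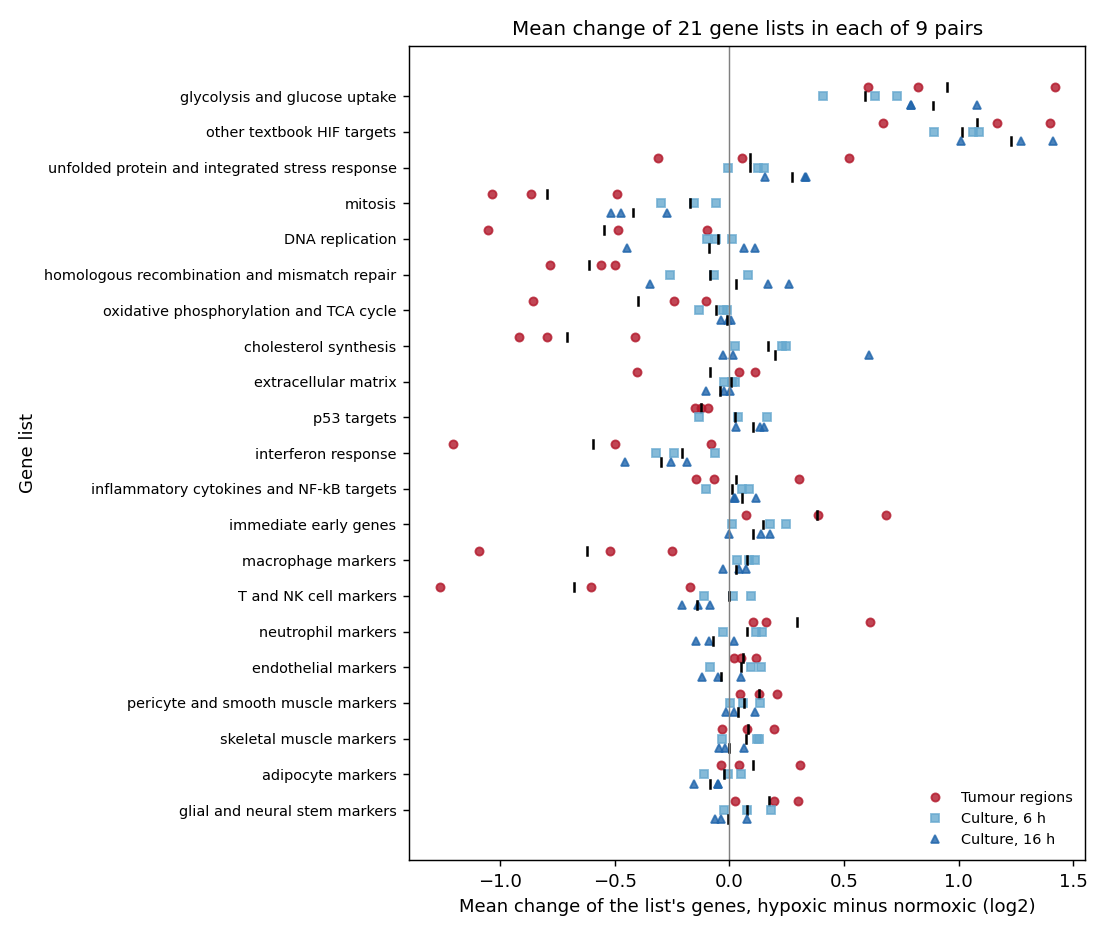
Mean change of each of 21 gene lists between hypoxic and normoxic samples (x axis, log2) in each of 3 tumours, 3 pairs of 6 h cultures and 3 pairs of 16 h cultures, with 1 point per pair and a black bar at the mean. Glycolysis and HIF target genes lay above 0 in all 9 pairs, and cholesterol synthesis genes had a mean of -0.71 in tumours against 0.17 at 6 h and 0.20 at 16 h.

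In cultures, 6 h at low oxygen raised a small set of genes, many of them known HIF targets. Ankrd37 rose 5.34-fold, by 2.42 ± 0.21 log2 units (SE, n = 3 cultures per group, limma adjusted p = 0.000106). The adenylate kinase Ak4 rose by 2.15 ± 0.22, the angiogenic placental growth factor Pgf by 2.03 ± 0.20, glycogen synthase (Gys1) by 1.87 ± 0.20 and the pyruvate dehydrogenase kinase Pdk1 by 1.76 ± 0.16. Abhd18 rose by 1.96 ± 0.15, Ero1a by 1.65 ± 0.15, Bnip3 by 1.64 ± 0.11 and Car9 by 1.60 ± 0.19. The vasodilator peptide gene Adm rose by 1.79 ± 0.31 (adjusted p = 0.0327). Over all probe sets 50 were higher and 2 lower, and neither of the lower ones is listed with a gene here. The lower genes taken by unadjusted p did not pass the threshold without a block, led by the ribosome biogenesis factor Rrp9 at -0.61 ± 0.12 (adjusted p = 0.0660) and Hibch at -0.55 ± 0.11 (adjusted p = 0.0750). With the culture number as a block, the lower genes Cyp1a1 (adjusted p = 0.0176), Wdr46 (0.0348) and Nap1l2 (0.0396) passed.

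Among the 29 other HIF targets, 17 rose at 6 h over all probe sets and 26 when adjusted over the list alone, with a list mean of 1.02 ± 0.10 log2 units (SD over 3 pairs). Bnip3l, a second mitophagy receptor, rose by 1.04 ± 0.10 (SE). Of the 20 glycolysis genes 5 rose over all probe sets and 11 adjusted over the list alone, with a mean of 0.59 ± 0.17 (SD over 3 pairs). Slc2a1 rose by 1.42 ± 0.17, hexokinase 2 (Hk2) by 1.17 ± 0.11 and Pfkl by 1.08 ± 0.17 (SE). These were the lists whose camera call held with an estimated correlation (adjusted p = 0.000505 for HIF targets and 0.0193 for glycolysis with an estimated correlation). Vegfa was 1.04 ± 0.31 higher without passing (adjusted p = 0.607), and passed with the culture number as a block (adjusted p = 0.0125). Hif1a and Epas1 were at -0.05 ± 0.12 and -0.14 ± 0.11.

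A further 4 lists passed camera at 6 h with the preset correlation only. Interferon genes lay at -0.21 log2 units, with Tap1, a peptide transporter of antigen presentation, at -0.42 the single member past the threshold adjusted over the list alone. Mitosis genes lay at -0.17, with 14 of 17 lower, cholesterol synthesis genes at 0.17, with 11 of 13 higher, and immediate early genes at 0.15, with the endothelial and quiescence factor Klf2 at 0.42 ± 0.11 (SE) past the threshold adjusted over the list alone. No mitosis or cholesterol gene passed it. Their values were adjusted p = 0.0798, 0.585, 0.709 and 0.472 with an estimated correlation, in that order. The mitosis call was lost without the hypoxic culture 26 (-0.12, adjusted p = 0.148), the cholesterol call without the hypoxic culture 13 (0.12, adjusted p = 0.183), and the immediate early call without the normoxic culture 6 (0.10), the normoxic culture 13 (0.11) or the hypoxic culture 13 (0.13). The count of 52 probe sets became 32, 30, 32 and 27 without the normoxic cultures 6 and 13 and the hypoxic cultures 13 and 26, 33 with a log2 change of at least 1, and 6 when the spread was estimated over all 18 arrays. The calls of Adm and Pfkl were lost when any of 5 of the 6 arrays was left out.

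After 16 h at low oxygen the same kinds of genes stood higher and several mitosis and interferon genes fell. Ankrd37 rose 8.92-fold, by 3.16 ± 0.21 log2 units (SE, n = 3 cultures per group, limma adjusted p = 1.27e-05). Pgf rose by 2.62 ± 0.20, Ero1a by 2.27 ± 0.15, Adm by 2.22 ± 0.31, the glucose transporter Slc2a3 by 2.21 ± 0.23 and the cyclin Ccng2 by 2.03 ± 0.28. Insig2 rose by 2.01 ± 0.16, the glycogen branching enzyme Gbe1 by 1.98 ± 0.14, Abhd18 by 1.92 ± 0.15 and Ddit4, an inhibitor of mTOR signalling, by 1.87 ± 0.26. The chemokine gene Cxcl10 fell by 1.24 ± 0.22, Pter by 1.03 ± 0.15, cyclin B1 (Ccnb1) by 1.00 ± 0.17, the interferon-induced Ifit3 by 0.98 ± 0.19 and xanthine dehydrogenase (Xdh) by 0.92 ± 0.11. Pimreg, Alg8, the urokinase gene Plau, Sema3a and the mitotic kinesin Kif20a also fell, by 0.89 to 0.76. Over all probe sets 165 were higher and 28 lower.

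Of the 29 other HIF targets 22 rose at 16 h over all probe sets and 25 adjusted over the list alone, with a mean of 1.23 ± 0.20 log2 units (SD over 3 pairs). Of the 20 glycolysis genes 10 rose over all probe sets and 16 adjusted over the list alone, with a mean of 0.89 ± 0.17 (SD over 3 pairs). Examples were Pdk1 at 1.70 ± 0.16, Slc2a1 at 1.53 ± 0.17, Aldoc at 1.51 ± 0.15 and Hk2 at 1.24 ± 0.11 (SE). Car9 and Bnip3 rose by 1.54 ± 0.19 and 1.42 ± 0.11. Both lists kept their camera call with an estimated correlation (adjusted p = 0.00051 for HIF targets and 0.00409 for glycolysis with an estimated correlation). Vegfa was 1.25 ± 0.31 higher without passing (adjusted p = 0.106), and passed with the culture number as a block (adjusted p = 0.0021) or without the normoxic culture 28 (1.66, adjusted p = 0.0111). Hif1a and Epas1 were at 0.09 ± 0.12 and -0.14 ± 0.11.

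The 17 mitosis genes lay at -0.42 ± 0.13 log2 units at 16 h (SD over 3 pairs), with Ccnb1 and Kif20a past the threshold over all probe sets and 10 lower when adjusted over the list alone, among them the kinase Plk1 at -0.77 ± 0.18 (SE). The 18 interferon genes lay at -0.30 ± 0.14 (SD over 3 pairs), with Cxcl10 and Ifit3 past the threshold over all probe sets and these, Isg15 and Psmb8 lower when adjusted over the list alone. Both lists passed camera with the preset correlation and fry (fry adjusted p = 0.0212 for both), but had adjusted p = 0.127 with an estimated correlation. The 19 genes of the unfolded protein and integrated stress response lay at 0.27 ± 0.10, with Ddit3 (0.78 ± 0.18), Ppp1r15a (0.68 ± 0.19) and Herpud1 (0.59 ± 0.17) higher when adjusted over the list alone. Cholesterol synthesis genes lay at 0.20 ± 0.35, 12 of 13 higher, and T and NK cell markers at -0.14 ± 0.06, all 13 lower, in cultures that hold 9L cells. The T and NK cell list averaged 5.25 to 5.51 on these arrays, under the array medians, where background limits the signal. With the culture number as a block Isg15 (adjusted p = 0.0276), Plk1 (0.0233), Ddit3 (0.00441) and Herpud1 (0.0276) also passed over all probe sets. No cholesterol synthesis gene and no T and NK cell marker passed, and the 3 lists had adjusted p = 0.471, 0.510 and 0.471 with an estimated correlation.

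Calls at 16 h varied with single arrays. Without the normoxic culture 28 the lists past camera were 4 in place of 7, those lost being interferon (-0.22, adjusted p = 0.0574), cholesterol synthesis (0.13) and T and NK cell markers (-0.16), and without the hypoxic culture 28 the stress response (0.15), cholesterol synthesis (0.06) and T and NK cell markers (-0.13) were lost. T and NK cell markers were also lost without the normoxic culture 22 (-0.09), without the hypoxic culture 29 (-0.13) and after quantile normalization (-0.11). The count of 193 probe sets became 74, 109 and 89 without the normoxic cultures 22 and 29 and the hypoxic culture 22, 489 with array weights, 68 with a log2 change of at least 1 and 33 with the spread of all 18 arrays. Of the 26 named genes past the threshold, 8 lost the call without some array: Cxcl10, Ccnb1, Ifit3, Pimreg, Alg8, Plau, Sema3a and Kif20a, all of them lower genes.

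The response at 16 h was compared with that at 6 h as an interaction. No probe set differed by limma's test (0 at adjusted p = 0.05, smallest adjusted p = 0.982, 1194 at unadjusted p under 0.05). Glycolysis genes lay 0.30 log2 units further up at 16 h than at 6 h, HIF targets 0.21 and stress response genes 0.18, and mitosis genes lay at -0.25. These 4 lists passed camera with the preset correlation (adjusted p = 1.93e-07, 0.000320, 0.0104 and 0.00148), and none did with an estimated correlation (adjusted p = 0.734, 0.767, 0.786 and 0.786 with an estimated correlation). The number of lists was 7 without the 16 h normoxic culture 29 and 2 without the 6 h hypoxic culture 6, whose absence ended the calls of HIF targets (0.14) and the stress response (0.13) and left glycolysis genes at 0.19. HIF targets lay at 0.12 without the 16 h hypoxic culture 28. The stress response call also ended without the 16 h normoxic culture 22 (0.13), without the 16 h hypoxic culture 28 (0.06) or after quantile normalization (0.16), and the mitosis call without the 6 h hypoxic culture 13 (-0.15).

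The genes raised in culture were then followed in the tumours. By 1 probe set per gene, 41 genes rose at 6 h and 117 at 16 h, and 39 rose at both times. Independent lists would share 0.335. Both sets of calls came from the same fit and share its estimate of each gene's spread, so that number is only a rough reference. The 39 genes lay 0.87 ± 0.38 log2 units higher in hypoxic tumour regions (SD over 3 tumours), at 1.31, 0.60 and 0.71 in tumours 1, 2 and 3. Of the 39, 30 were higher in tumours, among them Bnip3, Ndrg1 and Ero1a, and of the 20 with a culture change of at least 1 log2 unit at both times all 20 were. limma's camera gave p = 2.99e-13 for the 39 genes, fry p = 0.0534 and camera p = 0.0911 with an estimated correlation. Across 14324 genes, which are not independent replicates, the tumour and culture changes correlated weakly, at r = 0.220 and rho = 0.191 for 6 h and at r = 0.121 and rho = 0.0266 for 16 h. The 6 h and 16 h changes correlated at r = 0.433 and rho = 0.192.

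**Figure D3:**
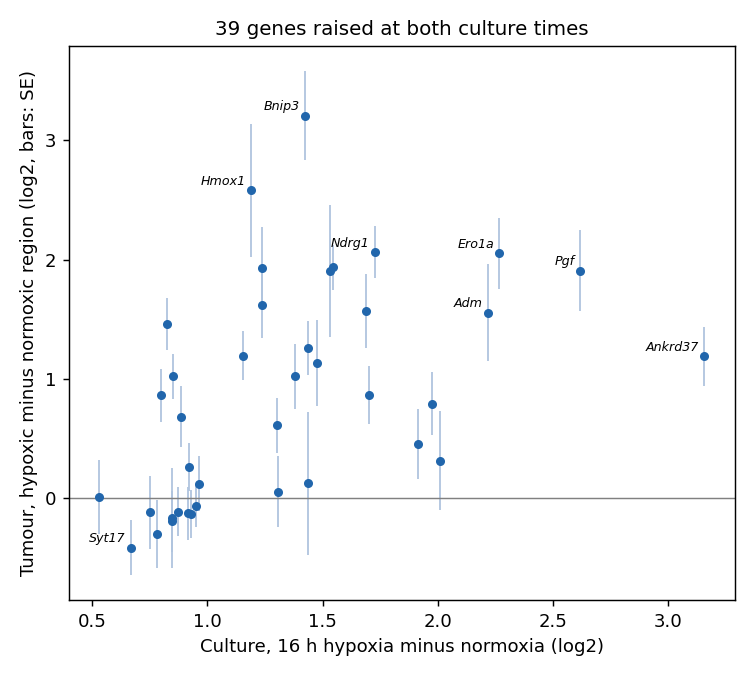
The 39 genes raised at both culture times, with the 16 h culture change on the x axis and the tumour change on the y axis (log2, bars are the SE, n = 3 tumours). Of the 39 genes 30 lay above 0 in tumours, and Bnip3 was the highest at 3.21.

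The tumour response was tested against the mean of both culture responses in a fit of all 18 arrays with 9 pairs as blocks. The tumour change of Atf3 lay above its culture change by 2.61 ± 0.23 log2 units (SE, limma adjusted p = 0.00161), that of Plau by 1.77 ± 0.24, Gnao1 by 1.44 ± 0.26, Cnksr3 by 1.41 ± 0.26 and Vapa by 1.33 ± 0.17. The tumour change lay below the culture change by the most for Slc44a2 at -2.89 ± 0.37, Ly6c at -2.80 ± 0.21, Slc25a40 at -2.41 ± 0.20, Cenpk at -2.39 ± 0.19 and Ost4 at -2.34 ± 0.20. Over all probe sets 49 differences were positive and 270 negative, and after quantile normalization 195 and 443. Tumour pairs varied more than culture pairs, with median residual SDs of 0.236 and 0.138 log2 units. When each system kept its own spread, 30 probe sets passed (2 positive, 28 negative, 29 of them shared), among them Atf3, Slc44a2, Ly6c, Slc25a40, Cenpk and Ost4. Plau, Gnao1, Cnksr3 and Vapa did not pass then (adjusted p = 0.0968, 0.165, 0.206 and 0.0952), and Gnao1 and Cnksr3 also lost their call without any of 6 of the 9 pairs. Without the pair block Gnao1 (adjusted p = 0.105) and Slc44a2 (0.133) did not pass.

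By list, 8 passed camera with the preset correlation in this comparison, all with the tumour change below the culture change. Cholesterol synthesis differed by -0.89 log2 units, with all 13 genes negative and 7 past the threshold adjusted over the list alone. Macrophage markers differed by -0.67 (6 adjusted over the list alone), T and NK cell markers by -0.61 (5), homologous recombination and mismatch repair by -0.59 (5), mitosis by -0.50 (8 negative and 1 positive), DNA replication by -0.48 (5), oxidative phosphorylation by -0.37 (2) and interferon genes by -0.34 (3). None passed with an estimated correlation (lowest adjusted p = 0.208 with an estimated correlation), and 4 passed fry: cholesterol synthesis, macrophage markers, mitosis and repair. Without tumour 3 the calls of DNA replication (-0.22), oxidative phosphorylation (-0.14) and interferon (-0.04) were lost, and macrophage markers lay at -0.44 and T and NK cell markers at -0.32. Without tumour 2 interferon genes lay at -0.60. The count of 319 probe sets ran from 44 without the 6 h pair 13 to 1365 without tumour 2, and was 772 and 649 without tumours 1 and 3, 58, 177 and 62 without the 16 h pairs 22, 28 and 29, 117 and 123 without the 6 h pairs 6 and 26, and 158 with array weights.

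Normoxic tumour regions were set against normoxic cultures to describe what the captured tissue held beside 9L cells, a comparison in which tissue, capture and culture go together. The lysozyme gene Lyz2 stood higher in the tissue, at a mean log2 level of 11.82 against 4.64 in the cultures (n = 3 against 6 arrays, limma adjusted p = 8.14e-13). So did the class II genes RT1-Da (11.83 against 5.27) and Cd74 (11.96 against 5.67), the interferon-gamma chemokine Cxcl9 (10.58 against 4.67) and the complement gene C1qc (11.57 against 5.95). The quinone reductase Nqo1 (6.11 in the tissue against 11.30), the replication protein gene Rpa3 (5.69 against 10.22) and the glutathione transferase Gsta1 (4.596 against 9.103) stood lower in the tissue. For these genes the lower level lay under the array medians, where background limits the signal, so the size of the difference is not exact. The growth factor gene Fgf7 was at -4.68 ± 0.43 and Akr1b8 at -4.54 ± 0.28 (log2 difference, SE). Macrophage markers were 2.94 higher on average, 15 of 16 past the threshold both over all probe sets and adjusted over the list alone, and T and NK cell markers 1.65 higher, all 13 past it on both counts. Both lists averaged under the array medians in cultures as well, at 5.24 to 5.51. The macrophage list was the one that held with an estimated correlation (adjusted p = 0.0151, against 0.0982 for T and NK cell markers with an estimated correlation).

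Mitosis genes stood at -1.42 in the tissue, with all 17 past the threshold over all probe sets and adjusted over the list alone, oxidative phosphorylation genes at -1.21 (17 of 19 and 18) and DNA replication genes at -1.20 (14 of 19 and 15). Repair genes stood at -0.99 (6 of 8 on both counts). These 4 lists had adjusted p = 0.0982, 0.0982, 0.171 and 0.172 with an estimated correlation. Interferon genes stood 0.89 higher (10 of 18 on both counts, adjusted p = 0.340 with an estimated correlation), a call lost without the normoxic region of tumour 3 (0.58, adjusted p = 0.0917). Endothelial markers were 0.77 higher, glial markers 0.65, neutrophil markers 0.55, skeletal muscle markers 0.52 and pericyte markers 0.47. HIF targets stood at -0.56, stress response genes at -0.81 and p53 targets at -0.47. After quantile normalization these 3 lists lost their calls at -0.24, -0.52 and -0.32, as did neutrophil, skeletal muscle and pericyte markers at 0.25, 0.25 and 0.26. These 8 lists had adjusted p = 0.123 to 0.199 with an estimated correlation. Probe sets of low signal shifted upward as a whole, with a median of 0.26 in the dimmest 25% and 0.47 in the next 25%, and those of the brightest 25% shifted by -0.62. Over all probe sets 11938 were higher and 5663 lower with a median shift of 0.24, a split that became 4371 and 8487 after median centring, 6032 and 4457 after quantile normalization and 5001 and 5081 after cyclic loess.

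**Figure D4:**
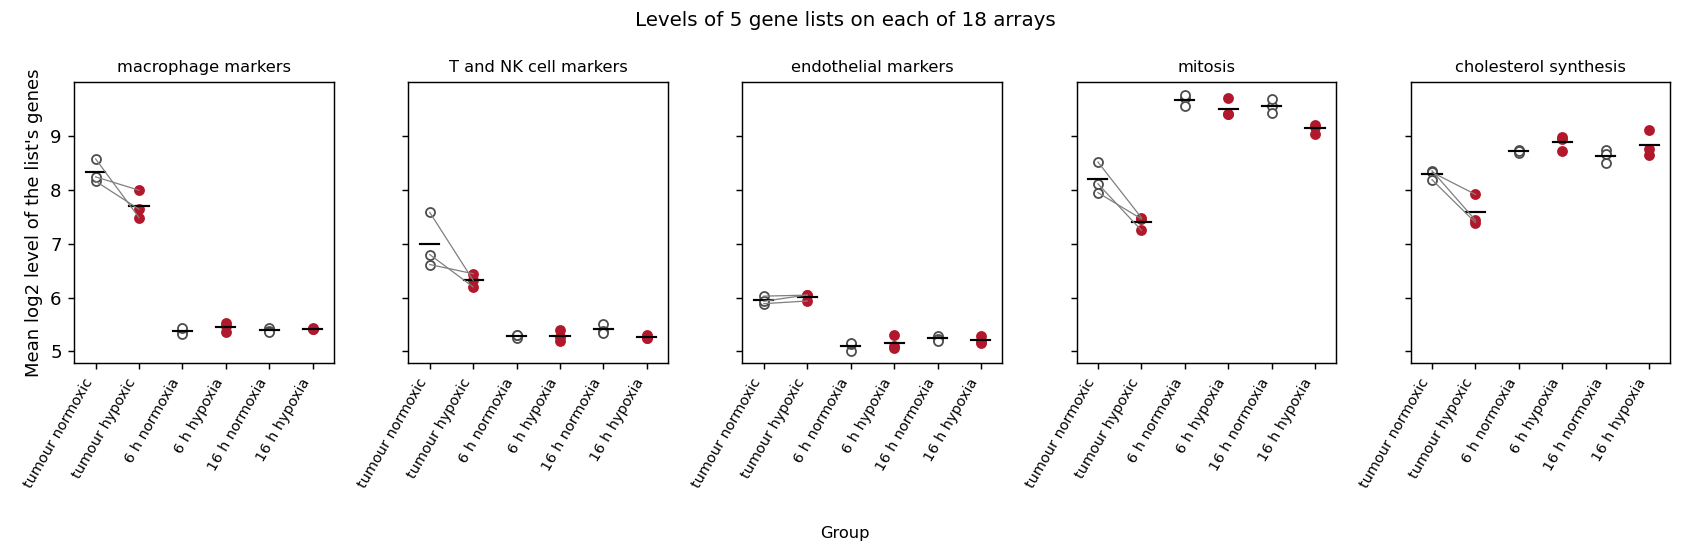
Mean log2 level of the genes of 5 lists (y axis) on each of 18 arrays by group (x axis), with filled points for hypoxic and open points for normoxic samples, a black bar at each group mean and grey lines that join regions of one tumour. Cholesterol synthesis genes had a mean level of 8.29 in normoxic and 7.58 in hypoxic tumour regions, against 8.64 to 8.88 in the 4 culture groups.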

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

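Each result here was singled out by a test of the difference between a pair of responses. Where a list value is set against a bound, its standard error is over the genes of the list. Genes can move together, so that error does not measure the spread between samples. The fit with a separate spread for tumours and cultures was chosen only after the result was seen, as were the tests by brightness, by the share of 9L or host cells and by the response in cultures, the tests of scaling and of the culture response as the whole cause, and the tests of a single tumour for mitosis and for DNA replication genes apart.

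The response at 16 h differed from that at 6 h by 0.296 log2 units for glycolysis genes, 0.215 for HIF targets, 0.184 for stress response genes and -0.250 for mitosis genes, by camera with the preset correlation. None of the 4 lists passed with an estimated correlation (lowest adjusted p = 0.734) or by fry (lowest adjusted p = 0.773).

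The tumour response differed from the mean culture response by 2.61 log2 units for Atf3, 1.77 for Plau, 1.44 for Gnao1, 1.41 for Cnksr3 and 1.33 for Vapa. It differed by -2.89 for Slc44a2, -2.80 for Ly6c, -2.41 for Slc25a40, -2.39 for Cenpk and -2.34 for Ost4. By list it differed by -0.501 for mitosis, -0.476 for DNA replication, -0.586 for homologous recombination and mismatch repair, -0.365 for oxidative phosphorylation, -0.892 for cholesterol synthesis, -0.343 for interferon genes, -0.674 for macrophage markers and -0.607 for T and NK cell markers. No list passed with an estimated correlation (lowest adjusted p = 0.208).

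Mitosis and DNA replication genes (36) lay lower in hypoxic regions, at -0.66, -0.28 and -1.04 in tumours 1, 2 and 3. The tables argue against a single tumour as the source for the 36 genes together, since the least negative tumour was at -0.282, and for mitosis genes (-0.488 at most), but it stays open for DNA replication genes, at -0.0974 in tumour 2, and they argue against a shift of bright against dim probe sets, since the mean was -0.654 relative to genes of the same brightness. A lower share of 9L cells stays open. Macrophage markers lay lower in every tumour (-0.248 at most), which argues against more macrophages in place of 9L cells but does not cover other host cells. Each hypoxic region correlated less with the mean of normoxic cultures than the normoxic region of its tumour. These correlations were 0.865, 0.884 and 0.875 against 0.892, 0.889 and 0.941 in tumours 1, 2 and 3. Quantile normalization left at least 89.5% of the change in each tumour (mean -0.66 ± 0.38 before and -0.63 ± 0.34 after, SD over 3 tumours), while neutrophil markers went from 0.29 to 0.22. This argues against differing distributions of values between the arrays as the whole cause. No list mean outside the pattern moved by more than 0.0761, so the correction was small. Other kinds of scaling were not tested for the change in each tumour. After median centring, 11 of 17 mitosis genes were lower adjusted over the list alone, against 13 as deposited. For DNA replication genes the counts were 5 of 19 against 6. A part of scaling in the change stays open. Tumour 2, at -0.266 after quantile normalization, lay above the bound set earlier, as its deposited value did. An effect of hypoxia on 9L cells is a candidate explanation for mitosis genes, which lay lower in every 16 h pair (-0.270 or below), and is open for replication genes, where 1 pair was at -0.448 and the others at 0.06 and 0.11.

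Macrophage, T cell and interferon genes (47) lay lower at -0.53, -0.16 and -1.18 in tumours 1, 2 and 3. A shift by brightness is argued against by a mean of -0.639 relative to genes of the same brightness. Quantile normalization left 93.7% or more of the change in each tumour (mean -0.63 ± 0.52 before and -0.61 ± 0.48 after, SD over 3 tumours). This argues against differing distributions of values between the arrays as the whole cause. The correction moved other list means by 0.0761 at most and so was small. Other kinds of scaling were not tested for the change in each tumour. Quantile normalization ended the calls adjusted over the list alone for macrophage markers (mean -0.62 ± 0.43 to -0.59 ± 0.37) and T and NK cell markers (-0.68 ± 0.55 to -0.69 ± 0.56). Their smallest limma adjusted p went from 0.0469 to 0.0768 and from 0.0434 to 0.0819, near the threshold on both sides. Median centring ended such calls for macrophage markers, T and NK cell markers and interferon genes. A single tumour stays open because tumour 2 lay at -0.162, within its standard error (over genes) of the bound. It also stays open because the normoxic array of tumour 3 stood apart (r = 0.941 with normoxic cultures, against 0.892 or below). Scaling as a part stays open because tumour 2 lay at -0.154 after quantile normalization, above the bound set earlier, as its deposited value did. Less host tissue of every kind also stays open, as endothelial and pericyte markers lay at 0.0988 but stood only 0.609 above the cultures in normoxic regions, too near the floor for the test, and for interferon genes an effect of hypoxia on 9L cells is a candidate explanation, since they lay lower in all 6 culture pairs (-0.0618 or below).

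Cholesterol synthesis genes (13) lay lower at -0.92, -0.41 and -0.79 in tumours 1, 2 and 3, and by level at 7.58 against 8.29 in normoxic regions and 8.64 to 8.88 in cultures. A single tumour is argued against by the least negative value of -0.412, and a shift by brightness by a mean of -0.658 relative to genes of the same brightness. Quantile normalization left at least 85.5% of the change in each tumour (mean -0.71 ± 0.26 before and -0.67 ± 0.27 after, SD over 3 tumours). This argues against differing distributions of values between the arrays as the whole cause. The correction moved other list means by 0.0761 at most and so was small. Other kinds of scaling were not tested for the change in each tumour. After median centring, 3 of the 13 genes were lower adjusted over the list alone, against 4 as deposited and 2 after quantile normalization. A part of scaling stays open with tumour 2 at -0.405 after quantile normalization, within its standard error (over genes) of the bound set earlier. Loss of host cells that express the pathway could not be excluded, since in tumour 3 the genes lay 0.296 above macrophage markers. Hypoxia acting on 9L cells as in the cultures is argued against as the whole cause, since all 6 culture pairs lay above all 3 tumours. The means were 0.17 ± 0.12 at 6 h and 0.20 ± 0.35 at 16 h against -0.71 ± 0.26 in tumours (SD over 3 pairs or tumours). The lowest culture pair (-0.0287) lay 0.384 ± 0.228 above the least negative tumour. That SE is over genes, which can move together, and does not measure the spread between samples. A small part and a longer or different hypoxia in tissue stay open, the latter untested.

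Other splits of the samples were run for each count. For tumours there are 4 splits and for each culture comparison 10, too few for a share under 0.05. In tumours 0 probe sets passed by limma (2496 at unadjusted p under 0.05) and 0 in the other splits, so that all 4 gave as many, while 11 lists passed, with 2 splits giving as many and 12 as the highest other. The genes raised in culture had a mean of 0.87, which 1 split reached, with 0.475 as the highest other. At 6 h the counts were 52 probe sets (1 split, highest other 0) and 6 lists (4 splits, highest other 7). At 16 h they were 193 (1 split, highest other 23) and 7 (3 splits, highest other 7), and for the difference of both times 0 (10 splits, highest other 0, with 1194 at unadjusted p under 0.05) and 4 (5 splits, highest other 6). For the tumour response minus the culture response, 319 probe sets were reached in 1 of 84 splits (highest other 3), a share under 0.05, and 8 lists in 23 of 84 (highest other 11), which is not. For normoxic tumours against cultures, 17601 probe sets were reached in 1 of 84 (highest other 11312, a count that points to a structure of the samples), a share under 0.05, and 15 lists in 9 of 84 (highest other 16), which is not. Each other split put tumour samples among the cultures, so a difference between the systems, in level, response or spread, can lower its count. The shares do not tell these apart and do not exclude chance for single probe sets.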

How the results depend on the processing

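Alternatives chosen only after the result was seen were leaving out replicates for lists, other settings for counts adjusted over the list alone, the separate spread for tumours and cultures, and scaling for the genes raised in culture. The number of arrays limits the precision, and signals near the background limit what dim probe sets can show. For the changes below the cause was not tested, except that fewer probe sets or arrays enter where some are left out. Over 2607 alternatives of 167 named gene values, 2377 kept direction and side of the threshold, 100 lost a call, 127 gained one and 3 turned. Over 747 alternatives of 61 list values the numbers were 632, 107, 1 and 7, and of 147 counts adjusted over the list alone 107 stayed within 1.5 times and 40 did not. Of genes and lists not printed, 20 of 2385 and 84 of 933 alternatives turned direction, at sizes up to 0.0798 and 0.211.

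Probe sets past the threshold in tumours were 0, and 1 without the dimmest 25%, 22 with a trended and robust variance, 1408 with all 18 arrays and the pair as a block, and 0 to 563 with a tumour left out (limma, 2496 at unadjusted p under 0.05). At 6 h they were 52, and 6 with all 18 arrays in 6 groups, 33 with a log2 change of at least 1 and 27 to 50 with an array left out. At 16 h they were 193, and 489 with array weights, 33 with all 18 arrays, 321 at adjusted p = 0.1, 68 with a log2 change of at least 1 and 74 to 171 with an array left out. For the tumour minus the culture response they were 319, and 638 after quantile normalization, 158 with array weights, 789 at adjusted p = 0.1, 30 with a separate spread and 44 to 1365 with a pair left out. For normoxic tumours against cultures they were 17601, and 10489 after quantile normalization, 10082 after cyclic loess, 9262 without the dimmer 50%, 10568 for probe sets with 1 symbol and 14352 to 18372 with a replicate left out.

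Lists past the threshold by camera with the preset correlation, with an estimated correlation and by fry were 11, 0 and 0 in tumours, 6, 2 and 2 at 6 h, 7, 2 and 4 at 16 h, 4, 0 and 0 for the difference of both times, 8, 0 and 4 for the tumour minus the culture response, and 15, 1 and 19 for normoxic tumours against cultures. With a replicate left out they ran from 10 to 11, 4 to 8, 4 to 7, 2 to 7, 6 to 9 and 14 to 16. The mean of the genes raised in culture was 0.87 in tumours, p = 0.0911 by camera with an estimated correlation, and ran from 0.66 to 1.01 with a tumour left out.

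The replicate block by culture number gave 60 probe sets at 6 h and 268 at 16 h. Among named genes it added calls for Vegfa (adjusted p = 0.0125), Cyp1a1 (0.0176), Wdr46 (0.0348) and Nap1l2 (0.0396) at 6 h, and for Vegfa (0.0021), Ddit3 (0.00441), Plk1 (0.0233), Herpud1 (0.0276) and Isg15 (0.0276) at 16 h. Without the block, the tumour minus the culture response had 237 probe sets, and Gnao1 (0.105) and Slc44a2 (0.133) lost their calls. The block changed no other call of a named gene and no list call by camera.

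Some values, or the side on which camera placed a list, turned direction. In tumours Epas1 was at -0.0037 after cyclic loess. At 6 h Hif1a ran from -0.15 to 0.0588 with an array left out. In tumours stress response genes, placed lower by camera, were placed higher by fry (mean 0.0891) and after quantile normalization (0.130), and ran from -0.127 to 0.288 with a tumour left out. Endothelial markers were at -0.0060 after quantile normalization. With a tumour left out, extracellular matrix ran from -0.181 to 0.0757 and inflammatory genes from -0.106 to 0.118. Adipocyte markers stayed positive on average, at 0.0045 to 0.176, but camera placed the list lower without tumour 3 (0.0045).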
